A study of Drosophila melanogaster with 3 samples.

How the data were processed

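The series measured where the protein encoded by cropped (crp) sat on the Drosophila melanogaster genome. crp is a basic helix-loop-helix factor of the AP-4 family, whose members bind the palindrome CAGCTG. Per the labels, the flies were a transgenic line that expresses crp with GFP at its C terminus, chromatin of whole mixed-sex embryos aged 0 to 24 h was sonicated to a size range of 200 to 800 bp, and the precipitation used an antibody against GFP. Whether the tagged gene was an added copy or the native gene is not given in the sources used here. The 3 samples were labelled as biological replicates of 1 group, so no comparison between groups was possible and the comparisons were between replicates, between peaks and the rest of the genome, and between classes of peaks. A control library was not analysed here.

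The data were peak lists, with no reads or counts. For each replicate and for the 3 replicates pooled the authors deposited a relaxed list of peaks and background, and 1 list of peaks past a threshold of the irreproducible discovery rate (IDR), which measures how far peak ranks are shared between replicates. Each list came on the dm6 and the dm3 build. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here, and the depth of each sample is unknown. The signal value of a peak is the authors' own, deposited on the scale of their peak caller, which moves with read depth, so it was used only to rank and describe peaks within a list. The −log10 q value of each peak was also deposited by the authors; it was the same, at the highest value of the list, for all IDR peaks and was not used. The summit of a peak was taken from the deposited offset in bases from the peak start. On dm6 each of the 5460 IDR peaks was also in the pooled list, and together they were its 5460 strongest peaks. The notes deposited with the lists name files among the sources of the dm6 IDR list that were not used here, so how the replicates entered it is not known in full.

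Coordinates are on dm6, counted from 1, and dm3 was used only for numbers of peaks and chromosome shares. Gene models came from the Ensembl release 115 annotation of dm6 and sequence from the RefSeq copy of the assembly, whose own annotation is FlyBase release 6.54. The 7 chromosome arms held 13968 protein-coding genes with 19275 distinct start sites. A summit was at a promoter when it lay within 500 bp of a start site of a protein-coding gene, and otherwise in the 5' UTR, coding exon, 3' UTR, intron or intergenic class, in this order. Summits of 2 lists were called shared within 100 bp. The strongest peaks of a replicate were its 5460 with the highest signal, the length of the IDR list. A site was counted at a summit when it lay whole within 50 bp on either strand, and the same width centred 500 bp away, on a side drawn at random with seed 1, served as flank. A motif present in the summit or the flank alone entered an exact two-sided McNemar test. Shares of features were tested by permutation with 10000 circular shifts of the summits within each chromosome, and agreement of replicates with 1000 shifts. Peak classes and gene lists were compared by Fisher's exact test, two-sided, chromosome shares by an exact binomial test against the share of start sites, and all families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Log2 odds ratios carry 0.5 added to each count. Intervals of shares are 95% Wilson intervals and cover counting error only; values over replicates are given as mean ± SD.

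The main tests, a first set of alternatives, 24 motifs and 30 gene lists were fixed before the data were examined, as was the rule for genes named in the text; tests and alternatives added later are named as such. The rule took crp, the gene with the nearest start site for the 15 strongest IDR peaks found among the strongest peaks of all 3 replicates, the 5 genes with most IDR summits inside them, and up to 4 members with the strongest promoter peak for the tracheal list and each list past the threshold. Of the listed gene names 13 matched no protein-coding gene of the annotation and were left out. Of the 30 lists, 13 were set by a pattern on the gene symbol, so family members with other symbols were not included. Alternatives covered the distance that counts as shared, the number of peaks, promoter and site windows, control sequence, gene assignment, gene length and number of start sites, and leaving out each replicate in turn. For the last, the summits shared by the strongest lists of the remaining pair replaced the IDR list.

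The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The tests of sites, hexamers, promoter share, gene lists, summit matching and chromosomes were run on simulated data first. The other statistics were not simulated. Apart from the chromosome test, random positions left out X and Y. The sets for the promoter test were smaller than the IDR list and were given fewer shifts. All of the 1685 CAGCTG sites planted at 5460 random positions were found, and no hexamer was called with nothing planted. Of 100 random sets of positions 4 passed the promoter test, and 1 of 100 sets drawn from the expected shares gave a called chromosome arm. Of 100 planted gene lists 77 were called, against 79.8 from the calculated power, and 7 of 2900 unchanged lists were called. A planted agreement of 61.3% of peaks was found as 61.7%.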

Results

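Chromatin bound by GFP-tagged crp was mapped in whole Drosophila embryos collected over 0 to 24 h, in 3 biological replicates of a single transgenic line. All statements concern binding in a mixture of embryonic stages, tissues and both sexes. The replicate lists held 30000, 28713 and 30000 relaxed peaks on dm6, the pooled list held 28145, and 5460 peaks passed the IDR threshold of the authors. These 5460 summits lay in 5050 distinct regions, because 796 summits shared a region with another summit. Peak signal, a value of the authors' peak caller, spanned 134-fold within the IDR list. The sequencing depth behind the peaks is unknown, and relative signal below means the signal divided by the median of the same list's 5460 strongest peaks.

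crp sites recurred between the 3 replicates, the strongest peaks most often. Of the IDR peaks, 2905 (53.2%) had a summit within 100 bp among the strongest peaks of every replicate, 106 in none, and 4447 (81.4%) had a match in the full lists of all 3. The IDR list was drawn from the pool of these same replicates. Matches of its peaks in them, and the correlation across its matched peaks below, are therefore partly built in. The sharing of the replicates' own strongest peaks does not use that list beyond its length. Each replicate's strongest peaks held 76.2% ± 4.61 (SD, n = 3) of the IDR peaks, with 71.5%, 80.7% and 76.3% in replicates 1, 2 and 3. Between replicates, the strongest peaks were shared for 62.8% (1 and 2), 72.1% (1 and 3) and 61.8% (2 and 3), a mean of 65.6% ± 5.68 (SD, 3 pairs). Circular shifts of one list gave means of 0.822% to 0.826%, and the permutation p was 0.001 for each pair, the smallest that 1000 shifts can give. Spearman's rho of the signal of matched IDR peaks was 0.757, 0.895 and 0.651 for the same pairs, taken across peaks, which are not independent replicates. Agreement rose to 87.3% among the 1000 strongest peaks of each replicate and was 33.8% over all relaxed peaks.

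Most crp summits lay at promoters. Of the 5460 IDR summits, 3975 (72.8%, Wilson interval 71.6 to 74.0) fell within 500 bp of the start site of a protein-coding gene, against 11.5% of shifted summits, a ratio of 6.34. The replicates gave 75.4% ± 6.33 (SD, n = 3), with 79.5%, 68.1% and 78.7%. Introns held 993 summits (18.2% against 39.3% of shifted summits), intergenic sequence 410 (7.51% against 30.1%), 3' UTRs 29 (0.531% against 4.50%) and coding exons 23 (0.421% against 13.9%). These 5 classes each had a permutation p of 1e-04, the smallest that 10000 shifts can give, and passed the adjustment over 6 classes. The 30 summits in 5' UTRs (0.549% against 0.791%) did not (permutation p = 0.0631). The shares of the 6 classes add up to the whole, so the excess at promoters by itself lowers the others. Their p values are therefore not separate evidence that a class was avoided. Of the 1485 summits outside promoters, introns held 993, intergenic sequence 410 and coding exons 23. The shifted shares above are of all shifted summits, 11.5% of them at promoters, so they are not on the same base. With promoters set aside on both sides, introns held a larger share than among shifted summits. Intergenic sequence and coding exons held a smaller one. No test was run on that base. The promoter share was 95.7% in the strongest quintile of IDR peaks by signal and 78.5%, 69.1%, 65.1% and 55.6% in the following quintiles. Summits sat close to and mostly upstream of the start: 29.6% of all IDR summits were within 50 bp of a start site and 45.1% within 100 bp. Of promoter summits off the start itself 79.5% lay upstream (78.2 to 80.7; 73.8% ± 8.07 over replicates, SD, n = 3), and the median position was −49 bp.

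The small chromosome 4 held fewer crp peaks than its share of start sites, and no large arm passed the threshold against start sites. Chromosome 4 had 21 IDR peaks, 0.385% of the list against 0.737% of annotated start sites (0.305% ± 0.0940 in the replicates, SD, n = 3). The Y chromosome had 0 of 5460 peaks against 0.119% of start sites. Both passed the exact binomial test (adjusted p = 0.00929 each), while 2L (18.7% of peaks), 2R (19.3%), 3L (20.3%), 3R (24.1%) and X (17.2%) did not, with adjusted p from 0.0874 for 2R to 0.795 for 2L. In the shorter lists without 1 replicate Y still had 0 peaks but was no longer past the threshold (adjusted exact p = 0.140, 0.0632 and 0.143 without replicates 1, 2 and 3), while the call for chromosome 4 was kept (adjusted exact p = 8.4e-05, 0.00373 and 6.1e-05). Against arm length in place of start sites, 4 and Y were again low and 2L was high (18.7% of peaks against 17.1% of length, adjusted exact p = 0.00555). Over all relaxed peaks replicate 1 had 1.57% on chromosome 4, above its share of start sites, and replicates 2 and 3 had 0.132% and 0.323%. How well the repeated sequence of Y and 4 can be mapped was not analysed here.

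The strongest crp peak of the IDR list lay at CG9175, and those at Tpr2 and HtrA2 followed. The summit at CG9175 (2L 6096698 to 6098966, minus strand) was at 6099023, 57 bp upstream of the start site, with 3 CAGCTG sites within 50 bp. It ranked first in the IDR list and in every replicate, with a relative signal of 52.0 ± 5.96 (SD, n = 3). Tpr2, which encodes a co-chaperone of Hsc70, had 43.1 ± 3.42 (summit 2L 16491346, 194 bp upstream) and HtrA2, a mitochondrial serine protease, 39.0 ± 7.15 (3R 14511556, 96 bp upstream). The next were puml with 34.3 ± 4.10 (2R 7812441) and RabGGTb, a subunit of the enzyme that prenylates Rab proteins, with 30.2 ± 7.75 (2L 2879095). The mitochondrial transcription factor gene mTTF had 31.5 ± 4.61 (2L 14348814), Slh, a gene of vesicle fusion, 30.7 ± 5.50 (2L 2492798), and milt, an adaptor that moves mitochondria along axons, 30.4 ± 0.554 (2L 7042330, at an internal start site). CG8520, CG5276, Tsp86D, jar, CG11050, CG10383 and Rfx completed the 15 peaks, with relative signals from 27.7 ± 3.28 for Rfx to 30.6 ± 3.52 for CG5276. All 15 were promoter peaks, 14 of them with the summit upstream of the start site and that of CG10383 69 bp downstream. CAGCTG lay within 50 bp of 12 of the 15 summits, and the nearest site was at 57 bp for Tpr2, 110 bp for Slh and 51 bp for CG10383.

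CAGCTG, the site of the AP-4 family, marked crp summits. It lay within 50 bp of 1560 of the 5460 IDR summits (28.6%, 27.4 to 29.8), against 4.63% of flanks, a ratio of 6.17 (exact McNemar p = 1.1e-259). The replicates gave 26.9% ± 6.89 (SD, n = 3), with 24.6%, 21.5% and 34.7%, against 5.06% ± 0.220 in their flanks. The nearest site was at a median of 18 bp from the summit, and 55.2% of the 1560 were within 20 bp. The stronger the peak, the more often it carried the site: 62.1% of the strongest quintile (59.2 to 64.9), then 33.6%, 17.4%, 15.1% and 14.7% (12.7 to 16.9) of the weakest. The strongest and weakest quintiles differed by 47.4 percentage points (Fisher's exact p = 6.2e-121; 46.9 ± 6.01 in the replicates, SD, n = 3). Within the 1000 strongest IDR peaks alone, of which 630 carried the site, the same split gave 9.50 points (Fisher's exact p = 0.0610). In the weakest quintile the share was still above that of its flanks, 3.02% (exact McNemar p = 3.1e-22). Several CAGCTG sites lay at 172 summits, 8.06% of the strongest and 1.37% of the weakest quintile.

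**Figure D1:**
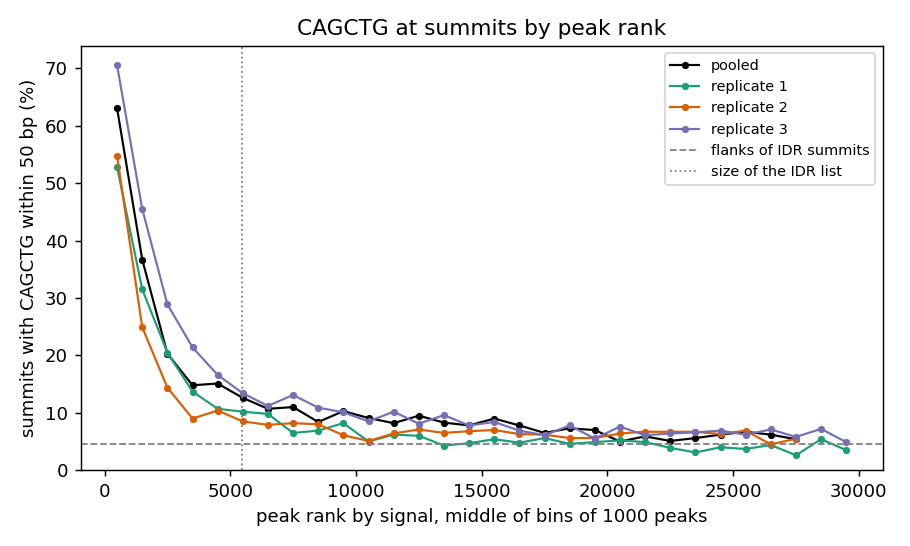
Share of summits (%, vertical axis) with CAGCTG within 50 bp in bins of 1000 peaks ranked by signal (horizontal axis), for the pooled list (black) and for replicates 1 to 3 (colours), with the share in flanks of IDR summits (dashed, 4.63%) and the length of the IDR list (dotted, 5460 peaks). The first 1000 peaks carried the site in 63.0% of the pooled list and in 52.8%, 54.7% and 70.5% of the replicates, and the shares approached the flank level beyond the IDR list.

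**Figure D2:**
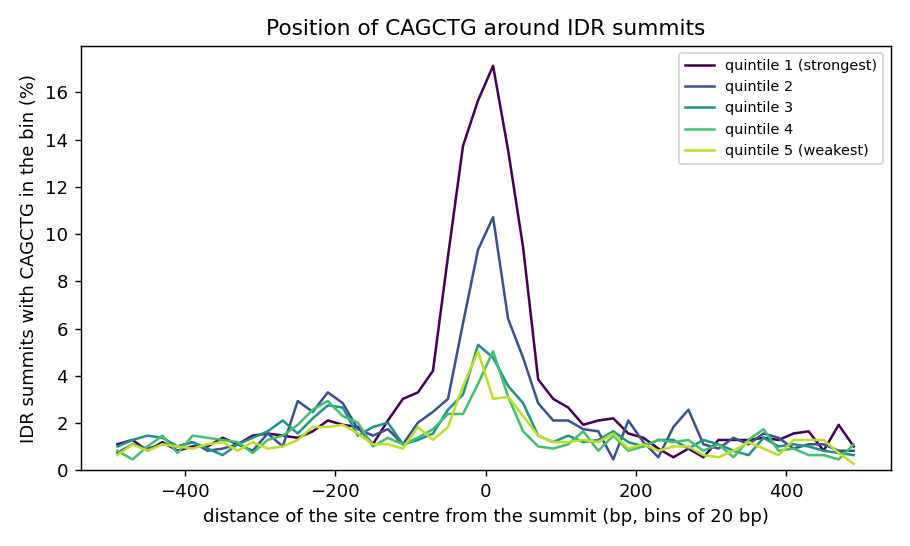
Share of IDR summits (%, vertical axis) with a CAGCTG centre in each 20 bp bin of distance from the summit (bp, horizontal axis; negative values are lower coordinates), by quintile of peak signal. In the strongest quintile 15.7% and 17.1% of summits had a site in the 20 bp below and above the summit, against 5.04% and 3.02% in the weakest.

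Promoter summits and other summits both carried CAGCTG above their flanks. The share was 29.99% of the 3975 promoter summits (28.6 to 31.4, flanks 4.91%) and 24.8% of the 1485 others (22.7 to 27.0, flanks 3.91%). The difference of 5.21 points (Fisher's exact p = 1.4e-04) was positive in 2 of 3 replicates, 2.32 ± 10.7 points (SD, n = 3), which is smaller than their spread. It turned round among peaks of like strength: within signal quintiles the Mantel-Haenszel odds ratio of a site at promoters against elsewhere was 0.627 (95% interval 0.537 to 0.733). The share was lower at promoters in every quintile. It was 62.0% of promoter summits against 63.8% of others in the strongest quintile, 30.9% against 43.4% in the second and 12.2% against 17.7% in the weakest. Without strata, by Fisher's exact test, the difference was −5.05 points (p = 0.0129) without replicate 2, 2.49 (p = 0.274) without replicate 1 and 8.11 (p = 6.1e-05) without replicate 3. In the 1000 strongest peaks it was −6.69 (Fisher's exact p = 0.484). With a narrower and a wider promoter window it was 5.72 and 8.33 (Fisher's exact p = 6.7e-06 and 2.2e-08). No direction was therefore established for the difference over peaks of all strengths. Among peaks of like strength the share was lower at promoters, a result given for the IDR list only.

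Summits also carried the motifs of housekeeping promoters. Of 24 fixed motifs, 11 were more frequent at summits than in flanks, 2 less frequent and 11 not past the threshold. The DNA replication-related element (DRE) TATCGATA was at 5.90% of summits against 0.366% of flanks (adjusted exact p = 4.7e-71), and its shorter relative CGATA, the site of the insulator protein BEAF-32, at 25.4% against 11.8%. The M1BP site GGTCACACT was at 2.55% against 0.110%, the core promoter motif GGTATTTT at 2.82% against 0.440%, and CAKCNCTA at 4.14% against 1.43%. Smaller in ratio were the excesses of TATAAA (14.6% against 9.98%), the GAGA factor site GAGAGAG (3.24% against 2.14%), the E2F site TTTSSCGC (2.58% against 1.72%), CATATG (4.51% against 3.11%) and CAGATG (5.29% against 4.25%). CACACACA (2.34% against 3.90%) and the E-box CACCTG (4.34% against 5.42%) were less frequent at summits than in flanks, which are richer in G+C. Against random positions of the same G+C, a control chosen after seeing the data, neither was less frequent (2.37% against 1.82% and 4.36% against 3.67%, adjusted exact p = 0.107 and 0.133). The calls for TATAAA (13.8% against 13.5%) and CAGATG (5.37% against 4.44%, adjusted exact p = 0.0644) ended, the other 9 higher motifs kept theirs, and CAAATG (8.51% against 10.8%) became less frequent. The remaining 6 E-boxes CAAATG, CAACTG, CAAGTG, CAATTG, CACATG and CACGTG and the sites of Zelda (CAGGTAG), GATA factors (AGATAA), Grh (AACCGGTT) and CREB (TGACGTCA), with TCATTCA, were not past the threshold, with adjusted exact p of 0.143 or more. DRE and M1BP sites were promoter motifs, at 7.82% and 3.40% of promoter summits against 0.741% and 0.269% of others. Neither the flanks nor the random positions were chosen at promoters, and promoters without a crp peak were not compared. The excess of promoter motifs can therefore follow from the place of most summits at promoters, and it was not tied to crp.

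A scan of all hexamers put CAGCTG first. It was followed by its overlapping neighbours ACAGCT (24.1% against 4.62%), AGCTGA (21.0% against 5.24%) and AACAGC (22.5% against 7.11%), and then by TATCGA (15.8% against 4.07%), CGATAG (11.8% against 2.69%) and ATCGAT (13.2% against 3.50%), of which TATCGA and ATCGAT are parts of the DRE and CGATAG contains CGATA. In all 436 hexamers were more and 695 less frequent at summits by the exact McNemar test with Benjamini-Hochberg adjustment. Summits were poorer in G+C than flanks (40.2% against 44.7%). Against random positions of the same G+C, 29.1% of the 5230 summits that could be matched had CAGCTG, against 3.92%. Outside promoters 60 hexamers were more and 47 less frequent, and CAGCTG (24.8% against 4.18%, with flank sides drawn anew) again ranked first.

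Genes for protein synthesis, energy metabolism and the cell cycle carried crp promoter peaks more often than other genes. Of 13968 protein-coding genes, 4657 (33.3%) had an IDR summit within 500 bp of a start site (31.3% ± 0.954 in the replicates, SD, n = 3). All 17 genes of the aminoacyl-tRNA synthetase list had one (Wilson interval 81.6 to 100%, adjusted exact p = 4.6e-08). That list was set by a symbol pattern, so synthetase genes with other symbols were not counted. A peak was also found at 23 of 29 ribosome biogenesis genes (79.3%, adjusted exact p = 2.5e-06), 72 of 92 ribosomal protein genes (78.3%, adjusted exact p = 9.9e-18) and 10 of 13 glycolytic genes (76.9%, adjusted exact p = 0.00411). The same held for 15 of 23 genes of Myc and growth control (65.2%, adjusted exact p = 0.00656), 26 of 40 of the cell cycle and replication (65.0%, adjusted p = 2.0e-04) and 36 of 56 of autophagy and the lysosome (64.3%, adjusted p = 1.1e-05). Subunits of the V-ATPase, the proton pump of lysosomes, followed with 19 of 33 genes (57.6%, adjusted exact p = 0.0104), and oxidative phosphorylation with 42 of 84 (adjusted exact p = 0.00411). The p values are from Fisher's exact test against all other genes, adjusted over 30 lists, of which 9 were higher, 6 lower and 15 not past the threshold. Whether a gene was active in embryos was not known here and was not matched, for the higher or the lower lists. A preference of crp for these groups and a difference between active and silent promoters can therefore not be told apart. A model with the number of start sites and gene length kept these 15 calls and added 6, the proteasome as higher and the neuronal, muscle, haemocyte, fat body and gut endoderm lists as lower. In the sets of 3377 to 3938 peaks shared by a pair of replicates some calls ended. Without replicates 1, 2 and 3 the ratio to other genes for Myc and growth control was 1.72, 1.35 and 1.57 (adjusted exact p = 0.110, 0.427 and 0.210), below that in the IDR list. For the cell cycle it was 1.65 without replicate 2 and 1.61 without replicate 3 (adjusted exact p = 0.0556 and 0.0891), against 1.95 in the IDR list. The loss of a replicate and the shorter list were not separated.

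The strongest promoter peaks of these groups reached high in the IDR list. The replication licensing gene dup had a relative signal of 24.4 ± 1.73 (SD, n = 3; IDR rank 23, summit 2R 15380704), E2f1, the transcription factor of S phase genes, 18.3 ± 3.74 (3R 21661036), the Cdc20 homologue fzy 14.1 ± 1.89 (2L 16310768) and the mitotic kinase gene aurA 13.8 ± 1.18 (3R 11962928). Both genes of the tuberous sclerosis complex, which restrains growth, were bound, Tsc1 with 10.9 ± 2.49 (3R 24130277) and gig with 7.13 ± 2.03 (3L 20129168), as were slmb with 8.75 ± 1.47 and Mondo with 3.92 ± 2.29. Vha44 had 25.3 ± 3.56 (2R 16336725), and Vha36-1, VhaAC45 and VhaM9.7-c had 15.7 ± 2.07, 11.3 ± 1.11 and 5.96 ± 0.988. UQCR-C1 of respiratory complex III had 18.1 ± 2.89 (3R 14890213), and the complex I genes ND-B18, ND-19 and ND-B17 had 17.4 ± 2.58, 13.1 ± 3.11 and 13.1 ± 2.23, each with CAGCTG within 50 bp. Among glycolytic genes Eno had 13.1 ± 2.98, Pfk 10.5 ± 5.26, Tpi 6.45 ± 1.70 and Ldh 4.98 ± 1.16. TrpRS and Vps16A, which start from opposite strands of 3R, shared a peak with 16.3 ± 1.87 (summit 3R 9266979). TyrRS, SerRS and CysRS had 15.2 ± 4.81, 13.3 ± 1.31 and 12.4 ± 1.64, and the lysosomal trafficking genes Vps33B, Vps60 and Vps13 had 16.7 ± 0.577, 14.8 ± 1.79 and 13.1 ± 5.23. The RNA polymerase I subunit gene Polr1B had 17.2 ± 1.92 (2L 404079), and l(2)k09022, Bka and Nnp-1 had 13.4 ± 2.54, 10.3 ± 2.52 and 7.87 ± 1.27.

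The ribosomal protein peaks were many, and few of them were strong or carried the site. Of the 72 bound ribosomal protein genes, 10 had a promoter peak in the strongest quintile and 11 had one with CAGCTG, while for oxidative phosphorylation these numbers were 24 and 21 of 42. The strongest, at RpL24-like (30.6 ± 3.52, SD, n = 3; 3R 11431813), was shared with CG5276 on the other strand; RpS28a, RpL37-1 and RpS23 followed. With only the 1000 strongest IDR peaks, the ribosomal protein genes differed from other genes by −1.55 points (adjusted exact p = 0.813), and the calls also ended for the cell cycle (adjusted p = 0.0661), Myc and growth control (0.813), glycolysis (0.122) and the V-ATPase (0.543). In those peaks the ratio to other genes was still 3.01 for glycolysis (4 of 13 genes) and 2.21 for the cell cycle (9 of 40), and lower for the V-ATPase (1.48) and Myc and growth control (1.28). When only peaks with CAGCTG counted, a choice made after seeing the data, oxidative phosphorylation was the 1 higher list past the threshold (21 of 84 genes against 10.9% of others, adjusted exact p = 0.00208). Aminoacyl-tRNA synthetases (23.5%), glycolysis (23.1%) and the cell cycle (22.5%) had shares near its own in fewer genes, with adjusted exact p of 0.217 or more. With each summit given to its nearest start site alone, Myc and growth control and the V-ATPase (adjusted exact p = 0.0596 each) and oxidative phosphorylation (0.0636) were not past the threshold, with ratios of 1.90, 1.68 and 1.42 to other genes, a little below those in the main test.

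Chemoreceptor, cuticle protein, testis-specific, histone and early segmentation genes were rarely bound. A promoter peak was found at 3 of 179 odorant, gustatory and ionotropic receptor genes (1.68%, adjusted exact p = 8.4e-26; Ir60e, Ir76a and Ir60b), 1 of 120 cuticle protein genes (0.833%, adjusted p = 6.5e-19; Lcp9) and 2 of 42 testis-specific genes (4.76%, adjusted p = 7.3e-05). The testis list held 1 strong peak, at Mst36Fa (17.2 ± 1.01, SD, n = 3; 2L 18677187), beside a weak one at Mst85C. None of 21 early segmentation genes had one in the IDR list (Wilson interval 0 to 15.5%, adjusted exact p = 8.1e-04), and each replicate's strongest peaks held 1 such gene, not shared by any pair of replicates (hry, bcd and hh in replicates 1, 2 and 3, named after their values were seen). Of 35 homeotic and homeobox genes 5 had one (14.3%, adjusted exact p = 0.0366), among them ap, tin, tup and oc, all with relative signals of 2.23 or less. Histone genes had 3 of 115 (2.61%, adjusted exact p = 1.7e-15), the replication-independent His3.3A, His2Av and His4r. Most histone genes lie in near-identical repeats, and how reads mapped there was not analysed here. The homeobox ratio to other genes was 0.428. Its call ended without replicate 1 (ratio 0.450, adjusted exact p = 0.137) or 3 (0.344, p = 0.0671), with nearest start sites (0.566, p = 0.323) and with any summit in the gene body or 500 bp upstream (0.788, p = 0.473). With the 1000 strongest peaks, which only 10.3% of other genes had, 0 of 35 homeobox, 0 of 21 early segmentation and 1 of 42 testis genes had one, and these calls ended (adjusted exact p = 0.136, 0.307 and 0.261). With CAGCTG peaks alone, which were also at few other genes, the numbers were 2, 0 and 2, and the calls also ended (adjusted exact p = 0.750, 0.507 and 0.635).

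Tracheal genes, listed because crp is known for its part in the branching airways of the fly, had promoter peaks at a share near that of other genes. There were 12 of 37 (32.4%, interval 19.6 to 48.5, against 33.3%, adjusted exact p = 1), led by bs, the fly serum response factor, with 9.87 ± 2.32 (SD, n = 3; 2R 24343677, 25 bp upstream of a start site, with CAGCTG). The others were weaker: sinu, a claudin, with 1.66 ± 0.347, sima, the fly HIF-1 alpha, with 1.23 ± 0.367, and bnl, an FGF, with 1.06 ± 0.503. The difference of −0.910 points turned positive with a window of 1000 bp (1.66 points), with nearest start sites (7.22) and with gene bodies (7.03), and was −11.1 points in the model with start sites and gene length, −7.55 with the 1000 strongest peaks and −3.76, −1.46 and −5.99 without replicates 1, 2 and 3, none past the threshold. Markers of single tissues, all present in whole embryos, gave 6 of 29 neuronal genes (20.7%), 4 of 25 muscle genes (16.0%), 4 of 13 glial genes (30.8%), 3 of 20 haemocyte genes (15.0%), 2 of 16 fat body genes (12.5%) and 1 of 16 gut endoderm genes (6.25%), with adjusted exact p of 0.0554 or more. All but the glial list were called lower in the model with start sites and gene length. By Fisher's exact test the fat body list was also called lower without replicate 1 or 2 (0 of 16 each, adjusted p = 0.0375 and 0.0405), but not without replicate 3 (adjusted p = 0.210). The gut endoderm list was called lower with nearest start sites (0 of 16, adjusted exact p = 0.0436). The proteasome had 23 of 48 genes (47.9%, adjusted exact p = 0.0790, called higher in the model with start sites and gene length). The Hippo pathway had 8 of 16 (adjusted exact p = 0.242), ecdysone genes 9 of 28 (32.1%) and basic helix-loop-helix factors 16 of 54 (29.6%). With any summit in the gene body or 500 bp upstream the Hippo list was called higher (11 of 16 genes, adjusted exact p = 0.0194). The Enhancer of split complex had 4 of 11 (36.4%), heat shock proteins 7 of 27 (25.9%), signalling ligands and receptors 8 of 31 (25.8%) and chorion and vitelline membrane genes 2 of 16 (12.5%), none past the threshold by Fisher's exact test.

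**Figure D3:**
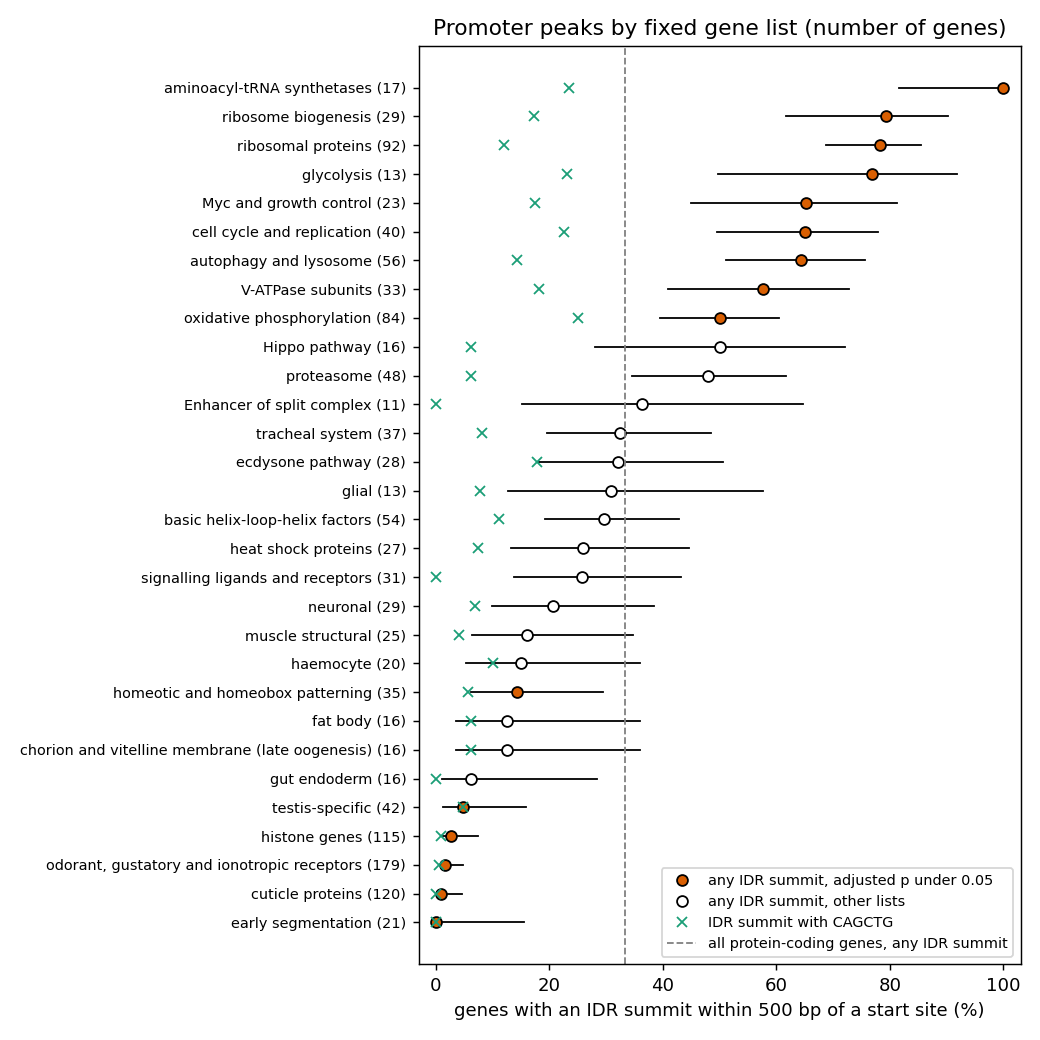
Share of genes (%, horizontal axis) of each of 30 fixed lists with an IDR summit within 500 bp of a start site (circles, with 95% Wilson intervals; filled where the adjusted p was under 0.05) and with such a summit that carries CAGCTG (crosses). The dashed line is the share of all protein-coding genes, 33.3%; aminoacyl-tRNA synthetases stand highest (100%) and early segmentation genes lowest (0%).

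The gene with the most IDR summits was crp itself. Its body (FBgn0001994, 2L 16263556 to 16287730, minus strand, 24.2 kb) held 16 IDR summits, 14 in introns and 2 at the promoter, and no other lay within 5 kb on either side. The replicates' strongest peaks gave 18, 12 and 18 summits (16.0 ± 3.46, SD, n = 3), and in replicate 2 CG1677 and ush had more, 14 each, and Raf as many. The strongest summit, at 16286161 in an intron 1569 bp downstream of the start site, had IDR rank 487 and a relative signal of 9.67 ± 6.46 (SD, n = 3), with CAGCTG at 16286184 to 16286189. Of the 16 summits, 4 had CAGCTG within 50 bp and 5 were in the strongest quintile. Among the 899 protein-coding genes of 15 to 40 kb the median was 0 summits and the highest besides crp was 15, at atos (2R 11619479 to 11640941). CG1677 followed with 12, and Raf, a kinase of growth factor signalling, the transcriptional regulator tara and ush, a partner of GATA factors, had 11 each, a tie at the fifth place. With only the strongest summit within 500 bp kept, a choice made after seeing the data, crp had 13 summits and the next genes 10. Without replicate 3 crp had 10.

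**Figure D4:**
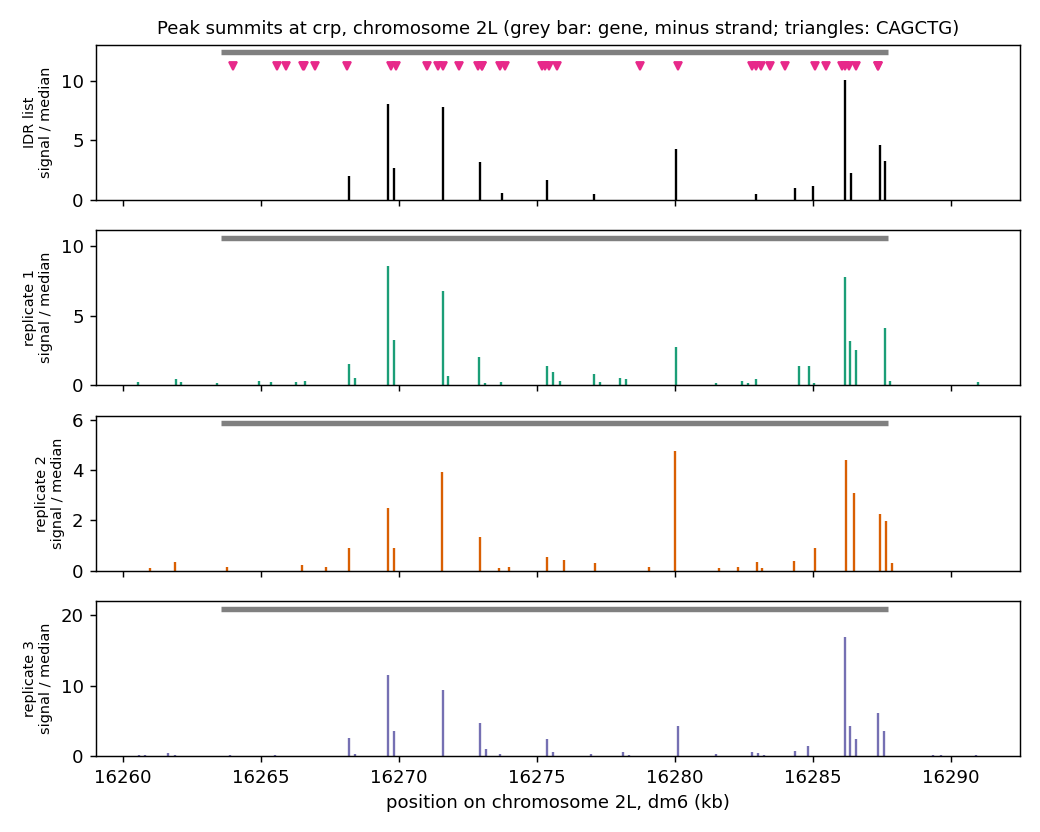
Summits at crp and 5 kb on either side (horizontal axis, position on 2L in kb, dm6) with their signal divided by the median of the list's 5460 strongest peaks (vertical axis), for the IDR list and the relaxed list of each replicate. The grey bar is the gene and the triangles mark its 37 CAGCTG sites; the highest IDR summit reaches 10.0.

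The IDR list on the older build dm3 was close in size to that on dm6, while some relaxed lists were shorter. The IDR list held 5418 peaks on dm3 and 5460 on dm6, with 0.388% and 0.385% on chromosome 4 and 17.1% and 17.2% on X. The lists of replicate 2 differed most, with 22967 peaks on dm3 and 28713 on dm6. The pooled lists held 25808 and 28145. No coordinate was converted between the builds.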

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

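The tests on sites 1 base from CAGCTG, on signal at active promoters, on second summits and on weak peaks around crp were chosen only after the result was seen. The samples form 1 group, so no biological explanation that rests on a comparison of groups was tested. Those weighed here rest on sequence, on the places and numbers of peaks and on matches between replicates.

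Peaks that the authors' threshold left out also carried CAGCTG above background, a signal in data outside the IDR list. Of the 5460 pooled peaks next below it, ranks 5461 to 10920, 10.1% had the site within 50 bp (Wilson interval 9.34 to 10.9) against 4.34% of flanks (exact McNemar p = 1.6e-32). The 5460 weakest pooled peaks had 5.95% against 3.81% (exact McNemar p = 2.1e-07).

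Most IDR summits, 3900 of 5460, had no CAGCTG within 50 bp. The 9 hexamers 1 base from CAGCTG together were at 33.2% of these summits and 40.4% of their flanks, a ratio of 0.821 (0.773 to 0.870), but the flanks are richer in G+C, which by itself can raise such hexamers there. Against random positions of the same G+C the shares were 34.1% and 31.8%, a ratio of 1.07 (1.01 to 1.14), and CAGATG alone was at 5.46% against 3.90% (adjusted exact McNemar p = 0.0135). Near sites therefore stay open, as a source of a small part of these summits. Only 14.8% (13.7 to 15.9) of summits without the site lay within 500 bp of a stronger one, so second summits beside a stronger peak could account for a small part only. General signal at active promoters remains open as a candidate explanation: within signal quintiles the odds ratio of lying at a promoter, for summits without against those with the site, was 1.59 (1.36 to 1.86), but this is the inverse of a comparison already in the report and no control precipitation was analysed here. Recruitment of crp through other proteins was not tested and could give the same value.

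The cluster of 16 summits in crp has 2 candidate sources, and neither was excluded. A dense run of sites was present: crp holds 1.53 CAGCTG per kb against a median of 0.458 in 898 genes of like length, at percentile 99.9. Of its 37 sites 4 (10.8%) had a summit within 50 bp, against 1.44% of all intron sites and 15.4% of promoter sites. The number of sites alone therefore falls short as a source. The share of them with a summit was also above that of intron sites, and only 4 of the 16 summits had a site within 50 bp. Extra copies of the region in the tagged line would raise signal without sites. The share of crp summits with CAGCTG differed by −15.6 points from that of other peaks of like rank (−33.4 to 11.8), too few summits to decide. This share depends on the 50 bp window: several crp summits counted as without the site had one centred at 48 to 63 bp. A wider window was not tried for this comparison. They would also raise weak peaks around the gene. In the 100 kb centred on crp, weak peaks stood at percentiles 98.9, 70.2 and 96.4 of such windows in replicates 1, 2 and 3. This was high in a pair of replicates and not in the other. The window includes crp itself, whose own weak peaks were counted, so the value cannot separate the surroundings from the cluster. Binding of crp to its own gene and added copies of the gene therefore cannot be told apart here.

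The promoter share was 68.1% in replicate 2, against 79.5% and 78.7%. Lower enrichment of crp sites may contribute, since 21.5% of its strongest summits had CAGCTG (20.5 to 22.6) against 24.6% (23.5 to 25.8) in replicate 1 and 34.7% (33.4 to 36.0) in replicate 3; yet replicate 1, close to replicate 2 in this share, had the highest promoter share. Background peaks stay open: 166 of the strongest peaks of replicate 2 lay outside promoters and matched no peak of the others, against 109 and 90 in replicates 1 and 3. They had CAGCTG in 2.41% against 7.83% of flanks, a ratio of 0.308 (exact McNemar p = 0.0490), below the flanks and so outside both outcomes set for the test, and at 3.04% of the list they are few beside the gap in promoter share.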

How the results depend on the processing

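Keeping only the strongest summit within 500 bp, counting only CAGCTG peaks, leaving histone genes out of the background, matching the motif panel on G+C, and leaving out replicates for the feature, motif, hexamer and chromosome results and for crp were chosen only after the result was seen. Of the values under alternatives that answer a comparison, 63 were the same, 18 moved, 2 lost their call and 3 reversed. Same meant that direction and call were kept or, without a test, that the value stayed within the replicate spread. For counts it meant a change within a set factor, so single calls could still be gained or lost. An example is the 15 gene lists called, which became 21 in the model with start sites and gene length. For single gene lists the numbers were 125 same, 30 weaker and 4 reversed. The promoter share kept its call under all 8 alternatives (64.2% to 96.4%), as did CAGCTG at summits under all 10 (17.4% to 63.0%). Agreement of the strongest peaks was 55.1% with summits within 50 bp, 72.6% within 200 bp, 78.5% with intervals that share a base, 87.3% for the 1000 strongest, 33.8% for all relaxed peaks and 61.8% to 72.1% without 1 replicate. The share of IDR peaks found was 68.5% within 50 bp, 82.0% with shared intervals, 92.7% in full lists and 99.1% for the 1000 strongest; rho was 0.651 to 0.895 without 1 replicate. A wider distance can only add matches; why the other settings moved these values was not tested. Without any 1 replicate 1 chromosome was called, in sets of fewer peaks. Hexamers called fell to 733 with a window of 25 bp. The strength difference was 9.50 points (Fisher's exact p = 0.0610) within the 1000 strongest peaks, which span less signal. Promoters against elsewhere gave −6.69 points in those peaks, −5.05 to 8.11 without 1 replicate, and an odds ratio of 0.627 within signal quintiles. The direction over all strengths changed with the replicate left out. In every signal quintile of the IDR list promoters had the lower share. Gene lists called were 7 with the 1000 strongest peaks and 4 with CAGCTG peaks alone, where fewer genes have a peak. The tracheal difference reversed to 1.66, 7.22 and 7.03 points with windows of 1000 bp, nearest start sites and gene bodies, and ribosomal proteins to −1.55 with the 1000 strongest peaks. Summits at crp were 10 to 14 without 1 replicate. Where no reason is given, the cause was not tested. Depth is unknown, so which weak peaks were missed for lack of reads cannot be said.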

Other observations

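The comparison of bases beside CAGCTG, the count of sites with a peak and the comparison of lower with higher coordinates were chosen only after the result was seen.

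Few of the CAGCTG sites of the genome carried a crp peak, and those at promoters did so most often. Of 62338 sites on the 7 chromosome arms, 1742 (2.79%, Wilson interval 2.67 to 2.93) had an IDR summit within 50 bp. The share was 15.4% (14.6 to 16.2) of 8533 sites at promoters, 1.44% of 20031 in introns, 0.587% of 15850 in intergenic sequence and 0.151% of 15916 in coding exons. The 5' UTR had 1.99% of 704 sites and the 3' UTR 0.690% of 1304.

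Bases directly beside the core went with binding. At promoters 54.5% of 693 sites with AA or AT before the core on both strands had a summit (50.8 to 58.2), against 26.7% of 2230 with it on a single side and 6.04% of 5610 with it on neither. The ratio of the first to the last was 9.03 (7.98 to 10.2, Fisher's exact p = 1.1e-208). A hypothesis is that crp may prefer an extended palindrome with AA or AT beside CAGCTG; the bases were picked from the same peaks, so an independent set of peaks would be needed. Elsewhere the shares were 12.1%, 1.88% and 0.264%. By the pair of bases before the core, at promoter sites only, AA (38.9%), AT (35.2%) and GT (27.6%) stood highest and GG (2.03%) lowest. Of the nearest sites at the 15 strongest peaks, 3 had this context on both sides (AACAGCTGTT at HtrA2, ATCAGCTGAT at Tpr2 and ATCAGCTGTT at RabGGTb), 10 on a single side, among them TTCAGCTGAT at CG9175, and 2 on neither (AGCAGCTGAC at CG11050 and TTCAGCTGAC at CG10383).

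CAGCTG also lay about 200 bp from summits more often at lower than at higher coordinates. Between 160 and 260 bp from IDR summits, 9.89% had a site at lower and 5.60% at higher coordinates (506 against 272 summits with a site on that side alone, exact binomial p = 3.9e-17). The shares were 15.6% and 5.82% in replicate 1, 8.79% and 5.33% in replicate 2, and 15.2% and 5.75% in replicate 3. With only the strongest summit within 500 bp kept they were 5.71% and 5.40% (exact binomial p = 0.533), so the difference came with summits beside a stronger one. The closest IDR summits were 199 bp apart. An effect of the peak caller on one side of strong peaks may be the source; it was not tested, and reads were not analysed here.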
